A study of Mus musculus with 89 samples.

How the data were processed

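RNA libraries of mouse nucleus accumbens were analysed from 2 deposited tables of exon skipping events. An event is an exon with its neighbouring exons, and each table lists the reads that include the exon and the reads that skip it in every library or run. Per the submitters' processing notes, STAR 2.4.1d, Bowtie2 and the genome builds mm9 and mm10 were used in the series, with no role stated for any of them, and the program that called the events is not given in the sources used here. The read counts, as deposited, are whole numbers joined by commas within a cell, with no library names, so 5 columns of the HSV table and 32 of the dCas9-SET2 table carry no sample. They were therefore compared as the 2 sets that each table defines, as planned before the data were examined for columns without names, and no condition was assigned to a set. The labels give 3 libraries to each of 3 HSV groups, so the table with 2 and 3 libraries holds part of them. ChIP, input and CUT&RUN samples were not analysed here.

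In the HSV table, the inclusion level is, per the file headers and as recomputed, the inclusion count over its form length against the skipping count over its form length. This held for 100% of values within 0.001. The form length of inclusion is the exon length plus 150 and that of skipping 150, so reads inside the exon body count toward inclusion. The p-value and FDR per event were made by the authors with a test not given in the sources used here, and the FDR matched a Benjamini-Hochberg adjustment of the p-value. The difference score deposited by the authors is the mean inclusion level of the 2-library set minus that of the 3-library set, and all differences are printed here the other way round. In the dCas9-SET2 table, the authors' dPSI score was the mean of differences between runs at the same position, leaving out those more than 1 SD from their mean and entering a run with no read as inclusion level 0, in 91.3% of events within 0.0001. The adjusted p-value of the authors (padj) followed a paired test on the same trimmed differences, with a Spearman correlation of 0.948 across events, which are not independent replicates, against 0.478 with no trimming. This rebuilt test was used only for alternatives, and the authors' deposited padj and dPSI are reported.

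The HSV table lists 27900 events in 9542 genes, of which 9430 were matched to symbols, and 5608 events in 3434 genes, 3433 of them matched, stand in the dCas9-SET2 table. Coordinates are printed as each table gives them, 1-based. The tables use different coordinates: 99.8% of exons of the dCas9-SET2 table but 13.1% of the HSV table lay inside the GRCm38 span of their gene, so no coordinate was compared between the tables. The median event had 102 reads per library in the HSV table and 4.78 reads per run in the dCas9-SET2 table.

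A count model was planned for both tables and was not fitted, because the counts stand joined in cells and were not taken as columns of counts. For the HSV table, limma on the logit of inclusion took its place, which had been planned as an alternative and as the main test for tables of inclusion levels alone. Events needed a mean of 20 reads per library and 10 reads of the rarer form, which left 7754. The logit of inclusion (0.5 added to each count) was fitted with limma 3.58.1 in R 4.3.3, with precision weights from the reads behind each value, for the 2-library against the 3-library set. Its moderated two-sided test was adjusted with Benjamini-Hochberg, and calls were made at 0.05. After weighting, limma estimated 1 spread shared by all events. Without a library of the 2-library set, the remaining one is assumed to vary like those of the other set. Gene coverage was the sum of inclusion and skipping reads of the deepest event of a gene with a mean of 20 reads per library. It was scaled by TMM factors (trims 0.3 and 0.05) and fitted with limma on log2 values with 0.5 added to each count and a spread trended on coverage, so fold changes of genes with few reads are understated. On data simulated from the libraries with 200 changed events or genes, the splicing fit made 49 calls, 1 of them false, and recovered 7.94% of changes of 0.5, 13.6% of 1 and 44.9% of 2 on the logit scale. With no change simulated it made 0 calls in limma, with 5.20% of events at unadjusted p below 0.05. The simulated spread of inclusion shrank with reads, as the weights assume, and held no spread between libraries that stays at high depth. The false calls in the real data can therefore be more. The coverage fit made 128 calls, 3 of them false, and recovered 11.4%, 80.3% and 100% of log2 changes of 0.5, 1 and 2. At this depth the splicing fit therefore missed most simulated changes of inclusion, also most of those of 2 on the logit scale. An event not called is thus no evidence of unchanged inclusion.

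In the dCas9-SET2 table the columns carry no sample names, and the runs behind the authors' test are not independent replicates. Summing the runs of a replicate had been planned. After seeing the data, distinct runs of a set were grouped by average linkage on the chi-square per degree of freedom of their read counts, over the deepest event of each gene with at least 10 reads in the pair, into as many groups as the labels give sample names per guide. The runs of a group were summed and taken as 1 library, and the 4 libraries of each set were fitted with limma in the same way, on 2298 events with a mean of 20 reads per library and 10 of the rarer form. No group was given a sample name or condition. On data simulated at this depth with 200 changed events, this fit made 66 calls, 1 of them false, and recovered 3.70%, 23.7% and 64.3% of logit changes of 0.5, 1 and 2, and with no change simulated it made 0 calls in limma, with 5.53% of events at unadjusted p below 0.05. Its simulated spread had the same form as for the HSV table, and the same limit. The runs at positions 4 and 8 were identical in both sets, and 15 distinct runs per set were used for medians, ranges and filters. Events with at least 5 reads per run on average and 10 of the rarer form were kept, which are 2389. The authors' padj was taken at 0.05.

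Before the data were examined, 15 gene lists were fixed: SR proteins, hnRNP and neuronal RNA-binding proteins, core spliceosome, H3K36 and chromatin, glutamate receptors and postsynaptic density, presynaptic, ion channels, medium spiny neuron with dopamine and cocaine genes, cytoskeleton and GTPases, astrocyte, oligodendrocyte, microglia and immune, vascular and neuron markers, and interferon response. Lists were tested with two-sided Fisher's exact tests on genes with a changed event against all other tested genes, adjusted over the 15 lists, and with 10000 random lists matched on events per gene and reads (one-sided). In coverage, a list's median was ranked among 10000 random lists matched in 20 bins of mean coverage. A further 3 lists (hypothalamus and septum, cortex, choroid plexus) were written after the coverage was seen and are used only in the closing observations. Direction was tested with two-sided exact binomial tests on 1 event per gene, exon classes with two-sided Fisher's exact tests and, within bins of inclusion level and reads, a Cochran-Mantel-Haenszel test, and intervals are 95% Clopper-Pearson intervals, which cover counting error only. Named genes were chosen by a rule fixed before the data were examined. It takes every tested Srsf11 event, then the 12 largest increases and 12 largest decreases of at least 0.10 in mean inclusion with no overlap between sets and adjusted p below 0.05. It also takes up to 4 called members of each list by p, and for coverage up to 4 called members of each cell type or interferon list with the 5 largest increases and 5 largest decreases. Beyond this rule, the medium spiny neuron, dopamine and cocaine genes and the SR and spliceosome genes given in coverage, and Rsrc2 and Srrm2 in the dCas9-SET2 table, were named after their values were seen. Where fewer than 6 events qualified by size, the 6 with the smallest p were named. Some genes that the rule names are not reported here, though all counts include them.

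Alternatives planned beforehand were other read minimums, 1 event per exon, a difference of at least 0.10, median-of-ratios scaling, no filter, reads summed over all events of a gene, and leaving out each library. Alternatives chosen after seeing the data were leaving out each library in the list tests, no weights, a robust spread trended on read support, thinned reads, the authors' deposited calls, scaling by totals, matched random genes and bins, no minimum of reads in the dCas9-SET2 table, alike runs summed, and forms of the rebuilt test without trimming, without empty runs or with the duplicated run counted once. Count models, replicate blocks, a fit of all HSV groups, comparisons by virus, overlaps at an unadjusted p below 0.01, and, for the dCas9-SET2 table, tests of gene coverage had been planned too and were not run. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.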

Results

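The series examined the histone mark H3K36me3, trimethylation of a lysine of histone H3 that is placed over transcribed gene bodies, and alternative splicing in the mouse nucleus accumbens, a brain region of reward. It holds 89 samples in 21 groups. Of these, 9 were RNA libraries of nucleus accumbens after herpes simplex virus (HSV) delivery of GFP, of Set2, or of a Set2 carrying the substitution R195G, with 3 libraries per group. Set2 is the methyltransferase that places H3K36me3. Another 32 were RNA runs after dCas9-SET2, a catalytically inactive Cas9 fused to SET2, with a guide to the splicing factor gene Srsf11 or a non-targeting guide. Each of these guides had 16 runs, under 4 sample names of 4 runs each. The other 48 samples were 24 CUT&RUN libraries of N2a cells (a mouse neuroblastoma line) and 15 H3K36me3 ChIP libraries with 9 inputs, which were not analysed here.

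The values came from 2 tables of exon skipping, each with the inclusion and skipping reads of every event in 2 unnamed sets of columns. The table of the HSV experiment had a set of 2 libraries and a set of 3 libraries, and neither set carries the name of a condition, so no virus was assigned to either. Its libraries held 8638249 and 8366275 reads over all listed events in the 2-library set and 8341849, 7455234 and 7428974 in the 3-library set. The table of the dCas9-SET2 experiment had 16 runs in each set, with 79799 to 106251 reads per run in the first set and 56946 to 84870 in the second. Libraries were compared as the table groups them. Nothing in the labels says that they came from separate animals, so the p-values rest only on these libraries, whose spread may be technical. In the weighted splicing fit of the HSV table, that spread was shared by all events and scaled by reads. An event's own spread between libraries thus did not enter its p-value separately, and deep events can have very small values. An exon of Enpp2 had inclusion levels of 0.394 and 0.109 within the 2-library set, yet an adjusted p of 3.05e-43 (limma). PSI below is the inclusion level, the fraction of transcripts that include the exon, and the direction is always the 3-library set against the 2-library set, or the second set against the first.

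In the HSV table, inclusion of single exons moved far and in both directions between the sets. The 94-nt exon of Kctd17 (chromosome 15, 78267331 to 78267424 as the table gives it) had PSI 0.548 and 0.526 in the 2-library set and 0.158, 0.139 and 0.14 in the 3-library set (adjusted p = 3.78e-31, limma). A 72-nt exon of Nova1, a neuronal splicing regulator, fell from 0.956 and 0.874 to 0.5, 0.572 and 0.55 (adjusted p = 6.99e-09). In the other direction, a 52-nt exon of Arhgap44, a GTPase-activating protein, rose from 0.293 and 0.339 to 0.677, 0.658 and 0.642 (adjusted p = 5.61e-15). A 147-nt exon of Tnrc6a, a component of the microRNA silencing complex, rose from 0.214 and 0.191 to 0.599, 0.611 and 0.68 (adjusted p = 2.22e-05).

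The same comparison found a 36-nt exon of Synrg, a partner of clathrin adaptors, at 0.905 and 0.947 against 0.543, 0.459 and 0.503. A 72-nt exon of Stxbp5l, a syntaxin-binding protein, stood at 0.658 and 0.832 against 0.253, 0.403 and 0.299. Inclusion was higher in the 3-library set for a 37-nt exon of Dnm1, the neuronal dynamin of endocytosis (chromosome 2, 32165971 to 32166007), at 0.396 and 0.282 against 0.748, 0.691 and 0.803. It was also higher for a 132-nt exon of Phc1, a Polycomb protein, at 0.342 and 0.283 against 0.683, 0.58 and 0.723. The adjusted p (limma) was 1.75e-11 for Synrg, 0.000759 for Stxbp5l, 2.09e-05 for Dnm1 and 0.00131 for Phc1. These 8 genes are among the 9, of the 12 largest increases and 12 largest decreases, whose call stayed without each of the 5 libraries in turn and with a spread fitted per read depth.

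**Figure D1:**
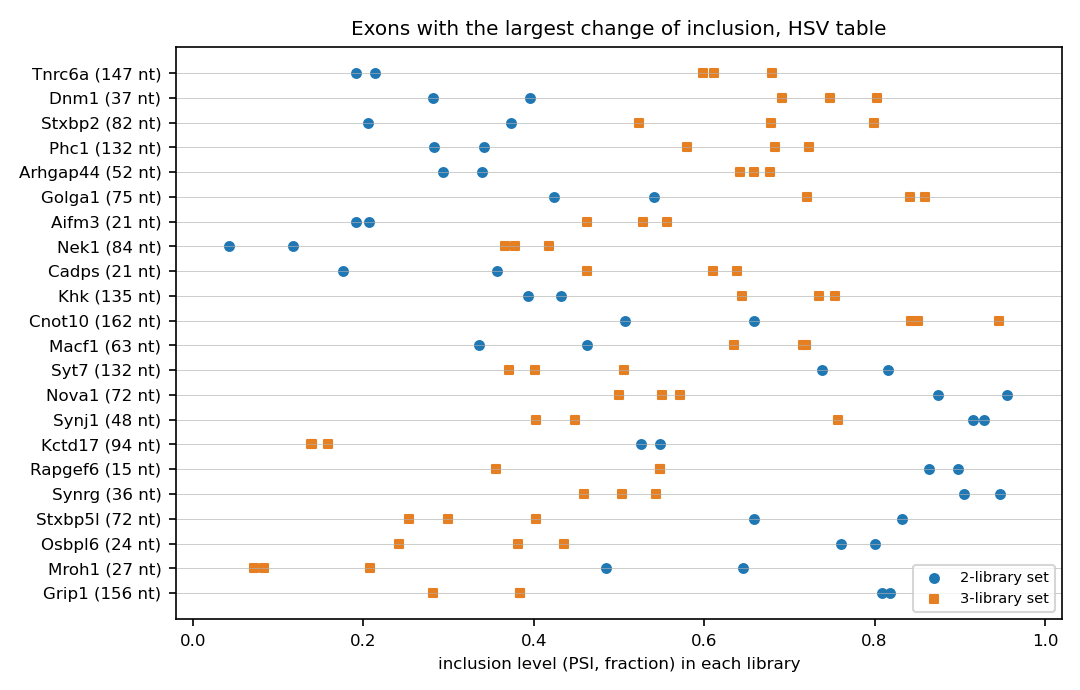
Inclusion level (PSI, a fraction, x axis) in each library for 22 of the 24 exons with the largest increases and decreases between the sets of the HSV table, named by gene and exon length (y axis). Circles are the libraries of the 2-library set and squares those of the 3-library set; for Kctd17 the circles lie at 0.548 and 0.526 and the squares between 0.139 and 0.158, and the calls of 14 of the 22 exons are lost in at least 1 alternative fit.

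The other 15 of the 24 lost their call in at least 1 of these fits, none with a change of sign, and 14 of them are given here. Without the first library of the 2-library set, the adjusted p of Cnot10 became 0.0967, of Grip1, a scaffold of glutamate receptors, 0.0606, of Stxbp2 0.161, of Khk 0.358, of Macf1 0.446, of Nek1 0.238, of Osbpl6 0.158, of Rapgef6 0.271, of the phosphoinositide phosphatase gene Synj1 0.128, and of Syt7, a synaptotagmin, 0.130. Without the second library of that set it was 0.0577 for Aifm3, 0.112 for Cadps, 0.431 for Golga1, 0.111 for Khk, 0.0547 for Macf1, 0.181 for Mroh1, 0.239 for Nek1, 0.113 for Osbpl6, 0.182 for Rapgef6, 0.179 for Synj1 and 0.0742 for Syt7. Without the first library of the 3-library set it was 0.0523 for Khk, 0.0546 for Macf1, 0.0617 for Nek1, 0.0692 for Osbpl6, 0.230 for Rapgef6 and 0.0576 for Stxbp2. Without the second it was 0.0905 for Golga1, 0.129 for Khk and 0.0818 for Macf1, and without the last 0.0595 for Golga1, 0.149 for Khk, 0.101 for Macf1 and 0.0979 for Nek1.

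Over all 7754 events tested, in 4194 genes, 286 events in 244 genes changed (limma, adjusted p below 0.05), 131 with higher and 155 with lower inclusion in the 3-library set. The difference was at least 0.10 in 216 of them, with a median of 0.159 and a largest value of 0.464. In 275 of the 286 (96.2%) the libraries of the sets did not overlap, which follows largely from calling them on the difference between these libraries. Over all events tested 27.6% did not overlap, against 20% by chance for 2 libraries against 3. The authors' deposited table called 974 of the tested events at an FDR below 0.05, and 270 events were called by both. Leaving out the first library of the 2-library set lowered the count to 150, and a total of 90 events in 77 genes were called in every fit that left out 1 library and with a spread fitted per read depth. The weighted fit shared a single spread among all events, and letting it vary with read depth gave 161 calls and dropping the weights 0 calls in limma, with 790 events at unadjusted p below 0.05.

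Cytoskeleton and small GTPase genes stood out among the lists fixed before the data were examined: 23 of 54 tested members (42.6%) had a changed event, against 5.34% of other genes (two-sided Fisher's exact test, adjusted p = 4.57e-14), and 26 changed when adjusted over the list alone. A 78-nt exon of Rap1gap, a GTPase-activating protein for Rap, fell from 0.779 and 0.786 to 0.455, 0.485 and 0.465. Inclusion rose for the 6198-nt exon of Ank2, an ankyrin that anchors membrane proteins to spectrin, from 0.163 and 0.131 to 0.275, 0.305 and 0.312, and for a 37-nt exon of the adducin gene Add1 from 0.179 and 0.176 to 0.354, 0.328 and 0.395. The adjusted p values (limma) were 1.10e-64, 6.83e-22 and 1.51e-20 in that order. Of the 23 genes, 12 had an event with higher and 12 an event with lower inclusion.

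Of the glutamate receptor and postsynaptic genes, 15 of 37 (40.5%, against 5.51% of other genes) had a changed event (adjusted p = 4.31e-09), 16 when adjusted over the list alone, with 12 genes lower and 3 higher. A 111-nt exon of Grin1, the obligatory NMDA receptor subunit, fell from 0.748 and 0.74 to 0.43, 0.45 and 0.495 (adjusted p = 2.15e-15, limma). The calcium/calmodulin kinase gene Camk2b lost inclusion of a 45-nt exon, from 0.766 and 0.768 to 0.612, 0.567 and 0.597 (adjusted p = 1.06e-41), while a 33-nt exon of Camk2a rose from 0.033 and 0.029 to 0.11, 0.159 and 0.122 (adjusted p = 1.44e-20).

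Presynaptic genes had 15 changed of 40 tested (37.5%, against 5.51%, adjusted p = 1.05e-08), 20 when adjusted over the list alone, 10 with higher and 7 with lower inclusion. A second event of the 37-nt Dnm1 exon rose from 0.363 and 0.361 to 0.651, 0.651 and 0.649, a 108-nt exon of the membrane-curving protein gene Bin1 from 0.435 and 0.472 to 0.675, 0.63 and 0.64, and a 36-nt exon of the clathrin light chain gene Clta fell from 0.883 and 0.863 to 0.708, 0.746 and 0.751 (adjusted p = 3.04e-23, 8.29e-07 and 1.88e-11 in that order, limma). Without the first library of the 2-library set the counts were 11 cytoskeleton, 8 postsynaptic and 9 presynaptic genes, and without the second 15, 11 and 7. The highest adjusted p of the 3 lists over the fits without 1 library was 0.00469. Against random genes matched on events per gene and read depth, all 3 had an adjusted p of 0.0005, from a one-sided permutation p of 0.0001, the smallest that 10000 random lists can give. In the same libraries, coverage of interferon genes was higher, that of medium spiny neuron genes mostly lower and that of microglia and oligodendrocyte genes mostly higher in the 3-library set, the last 2 depending on single libraries, as described with the gene coverage.

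Among hnRNP and neuronal RNA-binding protein genes 8 of 44 changed, 8 when adjusted over the list alone (adjusted p = 0.0125). They include Nova1 and a 122-nt exon of Matr3, a nuclear matrix RNA-binding protein, which rose from 0.827 and 0.815 to 0.917, 0.891 and 0.901. Hnrnpa2b1 and Hnrnph2 also had events with lower inclusion, and their adjusted p became 0.0715 and 0.252 without the first library of the 2-library set. The list's own call was lost without the first library of the 2-library set (adjusted p = 0.148), without the last of the 3-library set (0.163), with matched random genes (0.238), with a spread fitted per read depth (0.0506) and with the authors' deposited calls, where 11 of the 44 (25%, against 18.8% of other genes) had a called event (0.700).

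No other list passed in limma. Ion channel and transporter genes had 4 changed of 28 (adjusted p = 0.191), 7 when adjusted over the list alone, and passed with the authors' deposited calls, with 12 of 28 (adjusted p = 0.0111). Among the 4 was a 172-nt exon of the calcium pump gene Atp2b2, which rose from 0.092 and 0.112 to 0.198, 0.203 and 0.252. Itpr1 was called too, with adjusted p = 0.294 and 0.172 without the first or the second library of the 2-library set and 0.0700 and 0.0929 without the second or the last of the 3-library set. SR protein genes had 2 changed of 21 (adjusted p = 0.554), core spliceosome genes 2 of 17 (0.487), H3K36 and chromatin genes 1 of 33 (1), and medium spiny neuron, dopamine and cocaine genes 2 of 22 (0.554). The number was the same in each of these 4 lists when adjusted over the list alone. Most of these calls hung on single libraries. The SR gene Srsf3 had adjusted p values of 0.176 and 0.153 without the first or the second library of the 2-library set and 0.782 without the second of the 3-library set. Srrm1 had 0.678 without the second of the 2-library set and 0.216 and 0.0866 without the first or the last of the 3-library set. Without the first library of the 2-library set, Prpf18 and Sf1 of the spliceosome had 0.452 and 0.366 and Mef2a 0.452. Prpf18 had 0.287 without the second library of the 3-library set, and Sf1 and Mef2a 0.252 and 0.273 without its first. The chromatin remodeller gene Smarca4 had 0.200 without the second library of the 2-library set and 0.0576 without the first of the 3-library set. A 45-nt exon of Gnas, the stimulatory G protein gene, rose from 0.961 and 0.945 to 0.98, 0.98 and 0.982 (adjusted p = 1.64e-07, limma).

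Of cell type lists, oligodendrocyte genes had 2 changed of 7 (adjusted p = 0.175), 2 when adjusted over the list alone. A 78-nt exon of Mbp, a main protein of myelin, fell from 0.189 and 0.182 to 0.143, 0.127 and 0.136 (adjusted p = 4.27e-11, limma), and an exon of Enpp2 was called at 0.394 and 0.109 against 0.497, 0.474 and 0.59 but had adjusted p = 0.113 without the second library of the 2-library set. Astrocyte genes had 1 of 5, Slc4a4, also 1 when adjusted over the list alone (adjusted p = 0.487), whose own adjusted p became 0.379 without the first library of that set and 0.0949 without the first of the 3-library set. In limma, none of 9 microglia genes, 3 neuron markers and 11 interferon response genes changed, also none when adjusted over the list alone (adjusted p = 1 for each list), with 1, 1 and 0 genes at unadjusted p below 0.05, while the authors' deposited table called 0, 1 and 3 of them. No vascular marker gene had a tested event.

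Neither direction predominated. With 1 event per gene, 112 changed genes had higher and 132 lower inclusion in the 3-library set (45.9% higher, 95% exact interval 39.5 to 52.4, two-sided exact binomial p = 0.224). The authors' deposited calls gave 365 against 428 (46.0% higher, 95% exact interval 42.5 to 49.6, p = 0.0276). These p-values are against an even split. Of all tested events 47.8% were higher in the 3-library set, a share inside both intervals. Changed exons more often had a length divisible by 3, which keeps the reading frame: 229 of 286 (80.1%) against 3864 of 7468 other events (51.7%), an odds ratio of 3.75 (two-sided Fisher's exact test, adjusted p = 4.47e-22), and 2.34 within bins of inclusion level and read depth (1.09e-07). With the authors' deposited calls it was 592 of 974 (60.8%), an odds ratio of 1.45 (1.65e-07). Microexons of 27 nt or less made up 28 of the 286 (9.79%) against 376 of 7468 (5.03%), an odds ratio of 2.05 (adjusted p = 0.00153). That difference was not called with a spread fitted per read depth, where it was 13 of 161 events (adjusted p = 0.105).

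Srsf11, the splicing factor gene targeted in the other experiment, had 7 events in the HSV table, of which 3 were tested and none was called in limma. Its 117-nt exon (chromosome 3, 157686207 to 157686323) had PSI 0.224 and 0.105 in the 2-library set and 0.134, 0.166 and 0.131 in the 3-library set (adjusted p = 0.673, limma). The 2 events of its 109-nt exon (157687087 to 157687195) had adjusted p values of 0.568 and 0.523. The authors' deposited table called a 64-nt exon of the gene (157687662 to 157687725, FDR 0.0247), at 1 and 0.637 against 0.105, 0.26 and 0.584, which had 7 inclusion reads and 0 skipping reads in the first library and 5 and 2 in the second, below the minimum used here. Reads over its deepest event were 399 and 325 against 282, 312 and 336, a log2 difference of -0.13 (adjusted p = 0.591).

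Gene coverage, the reads over the deepest listed event of each gene, served as a partial stand-in for expression in the same HSV libraries. All 19 measured interferon response genes rose in the 3-library set, also 19 when adjusted over the list alone, with a median log2 of 4.00. The antiviral gene Oasl2 stood at 8.37 and 18.5 CPM (counts scaled to library size) in the 2-library set and 1028, 886 and 999 in the 3-library set, a 77.1-fold difference (log2 6.27, SE 0.23, adjusted p = 3.45e-09, limma). The interferon regulatory factors Irf7 and Irf9 rose by 5.19 and 3.38 on the log2 scale. The list's 19 calls stayed without each library in turn and under each scaling.

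Medium spiny neuron, dopamine and cocaine genes moved mostly the other way, with 17 of 31 fallen and 5 risen, 22 when adjusted over the list alone, and a median log2 of -0.60, below all 10000 matched random lists. The median was -0.40 without the first library of the 2-library set. Ppp1r1b, which codes for the dopamine-regulated phosphoprotein DARPP of striatal neurons, had a log2 of -1.75. The phosphodiesterase genes Pde10a and Pde1b, abundant in striatum, had -1.80 and -1.68, Rgs9 -1.79, Arpp21 -1.72, the dopamine receptor gene Drd2 -1.46, and the peptide precursor genes Penk and Tac1 -0.72 and -0.65. Those that rose include Gnas (log2 0.87), Htr2c (0.80), Ntrk2 (0.67) and Cartpt (1.34). Mef2d also fell, with adjusted p = 0.0874 without the first library of the 2-library set and 0.0685 without the first of the 3-library set, and Mef2c fell, with 0.0588 and 0.0506 without the second or the last library of the 3-library set.

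Glial lists lay mostly higher in the 3-library set, with counts and medians that moved with single libraries. Microglia and immune genes had 8 of 14 risen and none fallen, 9 when adjusted over the list alone (median log2 0.76), with Cd74, the invariant chain of antigen presentation, at 3.31, the protease gene Ctss at 1.42, Tmem119 at 1.40 and Aif1 at 0.84. Oligodendrocyte genes had 9 of 11 risen, 10 when adjusted over the list alone (median log2 0.50), with the myelin genes Mal at 0.78, Mobp at 0.69 and Mbp at 0.53. Astrocyte genes had 4 of 10 risen, 4 when adjusted over the list alone, with a median log2 of 0.30, and these were the water channel gene Aqp4 (1.09), Gjb6 (0.79), the glutamate transporter gene Slc1a3 (0.62) and Ntsr2 (0.33). With the first library of the 2-library set left out, 3 microglia genes rose and 2 fell, with a median log2 of 0.17, and 5 oligodendrocyte genes rose and 1 fell (0.34). Without the second of that set 11 microglia genes rose (1.34), and 4 astrocyte genes rose and 2 fell (0.18). The astrocyte median was 0.16 without the first library of the 3-library set. Without the first or the last library of the 3-library set 3 oligodendrocyte and 4 microglia genes were called, and without the second of the 3-library set 10 and 5. Aif1 had adjusted p = 0.0636 without the first library of the 2-library set, and Ntsr2 0.209, 0.153 and 0.155 without the second of the 2-library set, the first or the last of the 3-library set. The vascular gene Igfbp7, the only 1 measured, rose by 2.81, 1 when adjusted over the list alone. Of 7 neuron markers 3 rose and 2 fell, 7 when adjusted over the list alone. Rbfox3, which codes for the neuronal nuclear antigen NeuN, fell by 0.84, Syt1 rose by 0.58 and Gad2 by 0.44, and Chat (log2 0.92) had adjusted p = 0.120 without the first library of the 2-library set and 0.0536, 0.0752 and 0.0518 without each of the 3-library set. Without a library of the 3-library set 3 neuron markers were called.

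**Figure D2:**
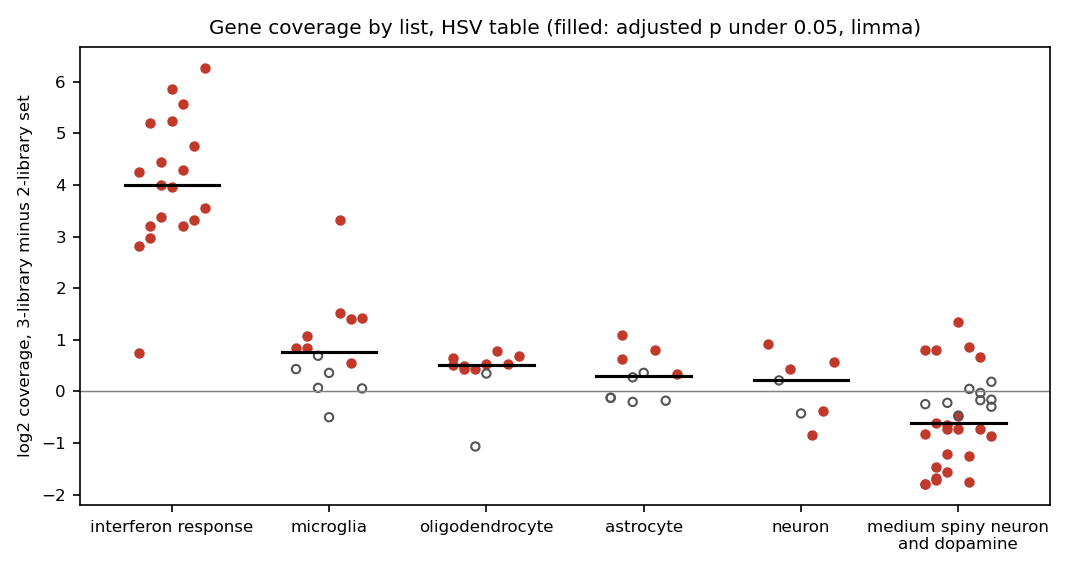
Log2 difference in gene coverage between the 3-library and the 2-library set of the HSV table (y axis) for genes of 6 lists fixed before the data were examined (x axis). Each point is a gene, filled where its adjusted p was below 0.05 (limma), and lines are list medians, at 4.00 for interferon response genes and -0.60 for medium spiny neuron and dopamine genes.

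Over all 8201 genes measured, 1859 changed in coverage (limma, adjusted p below 0.05), 1081 higher and 778 lower in the 3-library set, and 631 by at least 2-fold, of which 478 were higher. Libraries of the sets did not overlap in 49.8% of all genes, against 20% by chance. The 5 largest increases were Ifi44, with 2 and 6 reads against 555, 389 and 476, H2-Q6, with 1 and 1 against 119, 155 and 158, Slfn4, with 3 and 2 against 278, 365 and 164, Oasl2, with 34 and 75 against 4224, 3291 and 3646, and H2-Q7 (log2 6.26). H2-Q6 and H2-Q7 are near-identical class I histocompatibility genes, so their reads cannot be told apart with certainty. The 5 largest decreases were Ttr, the transthyretin gene of choroid plexus, with 1644 and 40145 reads against 49, 28 and 24, Cplx3, with 125 and 11 against 3, 6 and 2, Musk (log2 -2.61), Cd4 (-2.41) and Nr4a2 (-2.04). Without the first library of the 2-library set Cplx3 and Nr4a2 had adjusted p values of 0.381 and 0.392. Without the first of the 3-library set they had 0.0692 and 0.0903, and Cplx3 had 0.0780 without its last and Nr4a2 0.110 without its second. A gene enters with 1 event, so a change in splicing of that event can shift its reads, and 1366 to 2091 genes were called without each library in turn.

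Synaptic and RNA-processing lists split in coverage. Of glutamate receptor and postsynaptic genes 11 rose and 14 fell among 51, 29 when adjusted over the list alone, and 13 rose and 13 fell without the first library of the 2-library set. Of presynaptic genes 14 rose and 7 fell among 54, 22 when adjusted over the list alone, with 3 fallen without the first library of either set or the last of the 3-library set and 4 without its second. Ion channel genes had 12 risen and 8 fallen among 44, 24 when adjusted over the list alone, but 8 risen and 10 fallen without the second library of the 2-library set. Cytoskeleton and GTPase genes had 10 risen and 8 fallen among 64, 21 when adjusted over the list alone. That balance turned with single libraries, to 9 risen and 13 fallen without the second of the 2-library set and to 5 and 8, 7 and 8, and 6 and 8 without the first, second and last of the 3-library set. Of hnRNP and neuronal RNA-binding protein genes 4 rose and 16 fell among 51, 20 when adjusted over the list alone. The count was 13 without the first library of the 3-library set, 9 of them fallen, and 10 fell without the last of that set or the first of the 2-library set. H3K36 and chromatin genes had 3 risen and 5 fallen among 54, 6 when adjusted over the list alone, with 3 fallen when the first library of the 2-library set, or the second or the last of the 3-library set, was left out, and 9 with reads summed over all events of a gene. Of 29 SR protein genes 3 changed, 1 when adjusted over the list alone and 1 with reads summed over all events: Srrm4, a regulator of neuronal microexons, rose by 1.33, and Srrm2 (0.45) and Rsrc2 (-0.44) were called too. Srrm2 had adjusted p values of 0.123 without the second library of the 2-library set and 0.116 and 0.112 without the second or the last of the 3-library set, and Rsrc2 0.218 without the first of the 2-library set and 0.110 and 0.0639 without the second or the last of the 3-library set. Of 34 core spliceosome genes Ddx5 and U2af2 fell, by 0.54 and 0.48, the only 2 changed, also 2 when adjusted over the list alone, while 5 were called without the second library of the 2-library set. These 5 genes were named after their values were seen, since 5 or fewer changed in their lists. Scaling by totals moved counts too, to 15 risen and 4 fallen presynaptic genes and to 3 risen and 3 fallen H3K36 and chromatin genes.

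Genes with a changed exon more often changed in coverage too, 95 of 244 (38.9%) against 919 of 3950 other genes (23.3%), an odds ratio of 2.10 (two-sided Fisher's exact test, p = 1.24e-07). The genes were not matched on reads, and more reads make both kinds of call easier. A change in inclusion of the deepest event can also shift the reads counted as coverage, so the 2 kinds of call are not independent. Of the 286 changed events, 173 lay in genes with no change in coverage called and 264 in genes whose coverage differed by less than 2-fold.

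In the dCas9-SET2 table, the runs of each set were put into 4 groups by likeness of their read counts, a number taken from the sample names per guide. With the groups made on a random part of the genes, the chi-square per degree of freedom over the other genes was 1.36 to 1.76 in the 42 pairs of runs within a group and 1.77 to 3.13 in the 168 pairs between groups of a set. By mean silhouette over those genes, 4 groups parted best among 2 to 8 in the second set (0.295), while in the first set 2 did (0.184, against 0.170 for 4). The groups were positions 1 to 4, 5 to 7, 9 to 12 and 13 to 16 in both sets, with the copy at position 8 counted once with position 4. The table does not name them, and runs within a group still differed by more than sampling noise, which gives a value of 1. Runs of a group were summed and taken as 1 library, a step chosen after seeing the data, and the 8 libraries were compared as sets of 4 (limma). Of 2298 events tested, 1 was called, a 123-nt exon of Mbp, and 131 (5.70%) had an unadjusted p below 0.05. No event was called in limma with a spread fitted per read depth or without weights, where 142 and 126 had an unadjusted p below 0.05. Mbp had PSI 0.263, 0.247, 0.225 and 0.238 in the first set and 0.212, 0.207, 0.152 and 0.175 in the second (adjusted p = 0.00180), and lost its call without the library of positions 9 to 12 of the second set (0.111), where 0 events were called and 119 had an unadjusted p below 0.05. Without the library of positions 1 to 4 of the first set 6 events were called, including Psap (7.90e-09) and Srsf3 (0.0185). Without positions 5 to 7 of the second set 4 were called, including Psap (0.000161) and Srsf3 (0.00217), and without positions 13 to 16 of that set 2, Mbp and Psap (0.00813), against 0.0671 for Psap and 0.248 for Srsf3 with all 8.

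The authors' test instead entered each run as a pair. Of the 150 calls it makes among events with enough reads, counted below, 147 were tested over the summed libraries, where 1 was called, 54 had an unadjusted p below 0.05 and 144 had the sign of the authors' dPSI. These events were selected on the same reads, so the shared sign and the low unadjusted p-values are no independent evidence. The calls that follow are the authors' and are not tests over the summed libraries.

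Srsf11, the gene the guide was aimed at, had 4 events in that table. Its 117-nt exon (chromosome 3, 158023243 to 158023359 in that table) had a median PSI of 0.344 in the first set, with runs from 0.133 to 0.846, and 0.534 in the second, with runs from 0.208 to 0.821, over 15 distinct runs in each. The authors' deposited table gave it a dPSI of 0.190 with padj = 0.0345, from 190 and 167 reads over all runs of the sets. With reads pooled over runs, PSI was 0.376 and 0.476, a difference of 0.0996 (two-sided Fisher's exact p = 0.0652, unadjusted). Over the summed libraries PSI was 0.414, 0.508, 0.424 and 0.192 in the first set and 0.539, 0.579, 0.397 and 0.478 in the second, and the exon was not called (adjusted p = 0.922, limma). The authors' call was also lost in a rebuilt form of the authors' test when a duplicated run was counted once (adjusted p = 0.0712). The 109-nt exon (158024123 to 158024231) had medians of 0.12 and 0.169 in the event with enough reads, with dPSI 0.067 and padj = 0.505 in the authors' deposited table and adjusted p = 0.953 over the summed libraries. Reads over Srsf11 differed by 0.25 on the log2 scale after scaling by totals, the 80.3rd percentile among the genes of that table.

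SR protein genes had the highest share of called genes among lists with at least 5 tested members. In the authors' deposited table, 6 of 18 (33.3%, against 8.48% of other genes) had an event with padj below 0.05 (two-sided Fisher's exact test, adjusted p = 0.0307), 6 when a rebuilt form of the test was adjusted over the list alone. They were Srsf3 (dPSI 0.136), Srsf6 (0.125), Srsf11 (0.190), Srsf2 (-0.0934), Rsrc2 and Srrm2, 5 of them higher and 1 lower in the second set. Cytoskeleton and GTPase genes had 11 of 52 called (21.2%, against 8.34%, adjusted p = 0.0307), 14 when adjusted over the list alone, among them Ablim1 (dPSI -0.212), Myo18a (-0.0904), Ank2 (-0.0970) and the dynein gene Dync1i2 (0.0999). With the duplicated run counted once, 3 SR and 4 cytoskeleton genes were called and neither list passed (adjusted p = 0.428 and 0.444), nor did they against random genes matched on events per gene and reads (0.213 and 0.637). Of the named genes, Srsf2, Srsf11, Rsrc2 and Dync1i2 lost their call with the duplicated run counted once (0.0681, 0.0712, 0.0925 and 0.0542). Over the summed libraries no gene of either list was called in limma, with 5 of 17 SR and 8 of 52 cytoskeleton genes at unadjusted p below 0.05 and 1 and 0 called when adjusted over the list alone.

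No event called in that table had runs of the first set apart from those of the second, so 5 of the 6 with the smallest padj are given as values from the authors' deposited table. Nktr had a dPSI of 0.405 (padj = 0.000345). Dnajc6, a clathrin-uncoating co-chaperone, had 0.125 (0.00140), Fkbp1a 0.0129 (0.00140), Mbp -0.0519 (0.00140) and Psap, the saposin precursor, 0.0875 (0.00219). The deepest of them were Mbp, with medians of 0.241 and 0.196 from 9988 and 6515 reads, and Psap, whose 9-nt exon had medians of 0.311 and 0.435 from 8754 and 5000 reads. Over the 8 summed libraries only Mbp was called. Nktr, Dnajc6, Fkbp1a and Psap had adjusted p values of 0.808, 0.922, 0.922 and 0.0671 there (limma).

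No other list passed in the authors' deposited table. The glutamate receptor and postsynaptic list had 6 of 28 called, all with higher inclusion in the second set, 6 when adjusted over the list alone (adjusted p = 0.123), including the scaffold genes Dlgap1 (dPSI 0.213) and Shank3 (0.0676), Abi1 (0.0540) and Grik2 (0.121). The hnRNP and neuronal RNA-binding list had 7 of 36, 13 when adjusted over the list alone (adjusted p = 0.123), including Hnrnpa2b1 (0.0298), Hnrnpd (0.0693), Hnrnpl (0.324) and Fmr1 (0.205), and these 2 lists passed over all events with no minimum of reads (0.0174 and 0.0184). Core spliceosome genes had 3 of 13 called, 3 when adjusted over the list alone (0.246), namely Prpf39 (0.324), Snrnp70 (-0.0283) and Prpf38b (-0.100). H3K36 and chromatin genes had 4 of 18, 5 when adjusted over the list alone (0.197), namely Morf4l2 (-0.0512), Zmynd8 (0.134), Ehmt2 (0.0969) and Zmynd11 (-0.0992). Presynaptic genes had 3 of 33, 3 when adjusted over the list alone (1), namely Ap2a1 (0.151), Cadps (-0.155) and Nrcam (0.115). The medium spiny neuron list had 2 of 12, 3 when adjusted over the list alone (0.576), namely Mef2d (0.0985) and Meis2 (-0.0277), and the oligodendrocyte list 1 of 4, Mbp, 2 when adjusted over the list alone (0.576). None was called among 13 ion channel genes, 3 astrocyte, 2 microglia and 2 neuron markers and 5 interferon genes (adjusted p = 1 each). When the rebuilt test was adjusted over the list alone these 5 lists had 0, 1, 0, 0 and 1, and at unadjusted p below 0.05 they had 4, 2, 0, 1 and 1. No vascular gene was tested. Of the named genes, Hnrnpd, Hnrnpl, Fmr1, Abi1, Grik2, Prpf38b, Morf4l2, Zmynd11, Nrcam, Mef2d and Meis2 lost their call with the duplicated run counted once (adjusted p = 0.0538, 0.0597, 0.121, 0.0552, 0.0566, 0.0708, 0.0517, 0.0912, 0.102, 0.0712 and 0.0597 in that order). Over the summed libraries none of the genes named in this paragraph was called except Mbp, and the named exon of Prpf39 was not tested there. With empty pairs left out of the rebuilt test, Prpf39 lost its call (adjusted p = 0.0579), as did Fmr1 (0.0573), Zmynd11 (0.0954) and Nrcam (0.0655). Pooled differences were smaller than dPSI for most, such as Hnrnpl (0.0819), Abi1 (0.0234), Nrcam (0.0564) and Zmynd11 (-0.0483). They were larger in size for Prpf38b (-0.131), Mef2d (0.102) and Mbp (-0.0555).

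Over the whole table the authors called 262 of 5608 events, in 242 genes, 118 with dPSI above 0 and 144 below. Among the 2389 events with at least 5 reads per run on average and 10 of the rarer form, the authors' deposited table called 150 in 138 genes, 88 above and 62 below 0, with a median size of 0.119 and 84 of at least 0.10. With 1 event per gene, 80 were higher and 58 lower in the second set (58.0%, 95% exact interval 49.3 to 66.3, two-sided exact binomial p = 0.0735 against an even split). Of all kept events, called or not, 1248 lay above and 1138 below 0 (52.3% above), a share inside that interval. Exons of 27 nt or less made up 15 of the 150 (10%) against 148 of 2239 others (6.61%, adjusted p = 0.259), and lengths divisible by 3 made up 95 (63.3%) against 1374 (61.4%, adjusted p = 0.665). The runs at positions 4 and 8 were identical in each set. A rebuilt form of the test called 247 events, 104 with that run counted once and 2 with no differences trimmed.

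**Figure D3:**
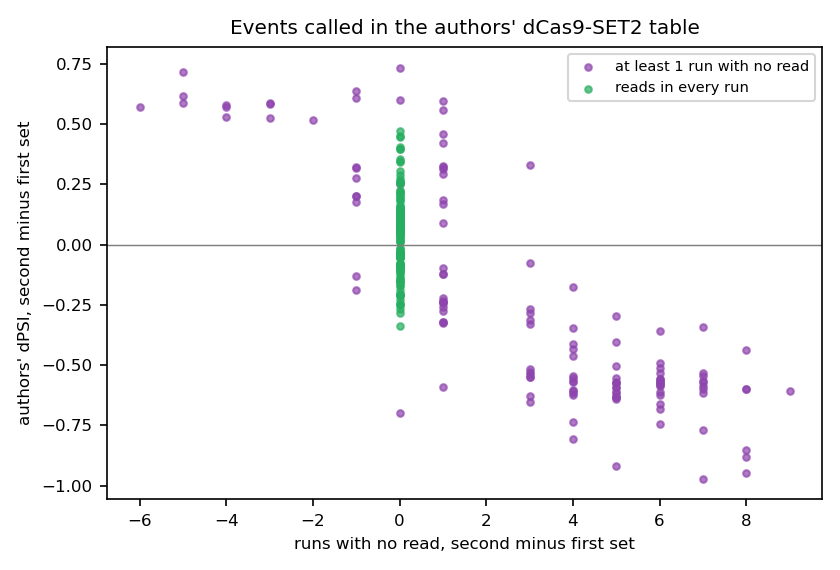
The authors' dPSI (second minus first set, y axis) of the 262 events called in the dCas9-SET2 table against the number of runs with no read, second minus first set (x axis). Purple points have at least 1 run with no read and green points have reads in every run; of 103 called events with more such runs in the second set, 91 have a dPSI below 0.

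The overlap of changed genes between the experiments did not pass its test. Of 1437 genes tested in both tables, 24 were changed in the HSV table and called in the authors' deposited dCas9-SET2 table, against 18.1 expected (one-sided Fisher's exact test, p = 0.0788). They include Ank2, Cadps, Dync1i2, Enah, Hnrnpa2b1, Mbp, Srsf3 and Tnrc6a. The overlap is by gene, without matching on reads or events per gene, and the exons can differ. The named exon of Ank2 had 6198 nt in the HSV table and 99 nt in the other, while that of Srsf3 had 456 nt in both. With no minimum of reads in the dCas9-SET2 table, 28 of 2466 genes were shared against 17.4 expected (p = 0.00606), and with the authors' deposited HSV calls 44 of 1437 against 34.5 (p = 0.0320).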

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

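The tests chosen only after the result was seen were those with the authors' deposited calls, no weights, a trended spread, thinned reads, scaling by totals, matched random genes, bins of inclusion and reads, lists without 1 library, no read minimum in the dCas9-SET2 table, no trimming, no empty runs, the duplicated run counted once, alike runs summed, pooled reads, and events with or without an empty run. Of the counts and tests of a comparison under an alternative, 33 stayed within 1.5 times the reported count or on the same side of the threshold, 11 moved further, 5 passed a threshold, 1 lost its call and 2 changed direction. Of those of named genes and lists 1064 stayed, 169 lost their call, 3 passed and 2 changed direction. The 286 splicing events of the HSV table became 974 with the authors' FDR, 161 with a robust spread trended on read support and 0 in limma without weights, where 790 events had an unadjusted p below 0.05. Leaving out 1 library gave 150 to 236, lowest without the first library of the 2-library set. The trended spread also ended the call for exons of 27 nt or less (adjusted p = 0.105, against 0.000676 to 0.0287 in the other alternatives). With the authors' calls the direction p against an even split became 0.0276, though their interval held the share of all tested events. For the 117-nt exon of Srsf11, not called in any fit, leaving out 1 library gave adjusted p values of 0.348 to 0.806 with the sign reversed without the first library of the 2-library set (0.749), and its coverage 0.263 to 0.970, reversed without the same library (0.970). Fits without 1 library had fewer libraries, and otherwise the cause was not tested.

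Of the 150 calls kept in the dCas9-SET2 table, 84 had a dPSI of at least 0.10 and 84 had at least 50 reads per 4 runs on average, while all events gave 262. Over summed libraries limma called 1 event. Rebuilt tests called 2 of the kept events with no trimming and 62 with the duplicated run counted once, and a Fisher test on pooled reads 25. The direction p became 0.0409 over all called events, 0.0824 with no read minimum and more events lower (the reverse side), 0.00659 for events with reads in every run, and 3.77e-08 for events with an empty run, again reversed. These p-values are against an even split, while 52.3% of all kept events lay above 0. The overlap of the experiments passed with the authors' HSV calls (p = 0.0320) and with no read minimum in the dCas9-SET2 table (0.00606), and the cause was not tested in this table either. No paired analysis was possible because the columns of both tables carry no replicate numbers, and the authors' pairing of runs by position, rebuilt here, is not one that the labels give. Count models, replicate blocks, fits with all HSV groups or by virus, overlaps at an unadjusted p below 0.01, and testing coverage in the dCas9-SET2 table were planned and not run. The median event of the dCas9-SET2 table had 4.78 reads per run.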

Other observations

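The tests of the lists of hypothalamus and septum, cortex and choroid plexus genes, and the tests of every explanation below, were chosen only after the result was seen. Genes of the hypothalamus and septum, in a list of 40 written after the coverage of the HSV table was seen, were higher in the 3-library set: 17 of 18 measured rose (limma, adjusted p below 0.05) and none fell, with a median log2 of 1.74. Resp18, a neuroendocrine secretory protein, had log2 2.67, Hap1, abundant in hypothalamic neurons, 1.79, the neurotensin gene Nts 1.69 and the transcription factor gene Lhx6 1.62. Reads of all 18 were present in both libraries of the 2-library set, 3 of the list's members are also in lists fixed earlier, and Hap1 stood at 154 and 230 CPM against 581, 735 and 636. Cortex genes, also in a list written afterwards, went the other way, with 11 of 18 fallen and 3 risen and a median log2 of -0.93 (-0.55, with 7 of 14 fallen, for those not looked at before the list was written), and 8 members of that list are also in lists fixed earlier. Nrgn, a postsynaptic calmodulin-binding protein, had log2 -1.86 and Itpka -1.17, while the 3 that rose were Cux2, Rasgrf2 and Tcerg1l. The call of Cux2 was lost without each library of the 3-library set. Members of this list thus moved both ways, and whether it reflects the share of cortex in the libraries was not tested.

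Libraries also differed within a set. Of 5 measured choroid plexus genes, 4 had a negative log2, with a median of -1.07, and 2 fell and 1 rose (limma). That rests on 3 genes seen before the list was written, and the 2 others had a median of 0.21. Without the first library of the 2-library set the median was -2.47, with 4 fallen, and without the second -0.25, with 1 fallen. The call of Clic6 was lost without the second library of that set (adjusted p = 0.566) and without each of the 3-library set (0.0966, 0.0936 and 0.131). Ttr, a main product of choroid plexus, had 1644 and 40145 reads in the 2-library set against 49, 28 and 24, Enpp2 567 and 3968 against 814, 594 and 631, Clic6 121 and 318 against 105, 103 and 80, and Calml4 3 and 122 against 4, 4 and 0. The exon of Enpp2 had a PSI of 0.109 in the library with the most Ttr reads and of 0.394 to 0.59 in the other libraries. In the dCas9-SET2 table, where no test of coverage was made, the 4 measured oligodendrocyte genes had a median log2 of -0.35 in the second against the first set and 5 interferon genes -0.37, at the percentiles 0.23 and 0.11 of random lists matched on reads, and 13 core spliceosome genes -0.18, at 3.76. SR protein genes had -0.01 and medium spiny neuron genes 0.02, at the percentiles 46.9 and 58.2. These percentiles rank genes on the reads of whole sets and hold no spread between libraries, so they are not tests of a difference between the sets.

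Splicing differed between the sets of the HSV table in 286 events, and the candidate explanations here are all of the libraries, since the sets carry no condition. With reads thinned to the smallest library total, 286 events were called, 272 of them the same. Library totals lay close, from 7428974 to 8638249 reads, so thinning removed few reads and is a weak test of unequal depth. Of the 286 events 264 lay in genes whose coverage differed by less than 2-fold. Only 631 of all 8201 measured genes changed by at least 2-fold, so this share cannot decide whether the gene's own coverage plays a part. Genes with a changed exon changed in coverage more often, 38.9% against 23.3% of other genes. They were not matched on reads, and a change in inclusion can itself shift the reads counted as coverage. That difference thus cannot decide the question either. Libraries that hold different shares of neighbouring brain regions remain a possible explanation. In coverage, the 13 hypothalamus and septum genes not looked at before their list was written had a median log2 of 1.69, above all matched random lists. Medium spiny neuron genes had -0.60, below all of them, and -0.40 without the first library of the 2-library set. Interferon genes differed more between the same sets, with all 19 risen and a median log2 of 4.00. These are coverage values, and whether any of them goes with the 286 splicing events was not tested. How virus and preparation relate to the sets is not known, so an effect of either stays open and no biological explanation was tested.

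Calls of the dCas9-SET2 table lay below 0 mostly where a run held no read: of 128 such events 94 had a dPSI below 0, against 50 of 134 with reads in every run. Entering empty runs as inclusion level 0 may account for this. With reads pooled over runs, where an empty run has no weight, 73 of the 128 lay below 0 (57.0%, 95% exact interval 48.0 to 65.7), against 73.4% by dPSI, and the median size of the difference was 0.156 against 0.555. Over all 2186 events with more empty runs in the second set 61.4% had a dPSI and 47.3% a pooled difference below 0, and over the 601 with more in the first set 29.3% and 50.4%. The second set had fewer reads, and whether its depth brought the empty runs was not tested. No biological explanation was tested.

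The number of calls in the same table depended on the test. The rebuilt test called 247 events as trimmed, and 2 with all differences kept, where 498 events had an unadjusted p below 0.05, so that trimming may set most of the count. A run entered at positions 4 and 8 could add to it, since 104 events were called with it counted once, below the 189 to 268 called when any of the 14 other pairs was left out. With whole groups of alike runs changing sides, 2 of 8 swaps, the real 247 included, gave at least as many calls. The other swaps gave 97 to 321 calls, with a median of 142. The trimmed test thus made many calls also where the sides did not follow the sets, and 8 swaps are too few for a share under 0.05. With alike runs summed 1 event was called, but a run-level test with all differences kept called 2 as well. Entering alike runs as separate pairs was thus not enough for the count without trimming. Whether it adds to the count of the trimmed test was not tested. Chance could not be excluded for the summed libraries: 12 of their 35 splits into 4 and 4 gave at least the 1 call of the real split, and the highest other gave 12. That split set positions 1 to 4 and 13 to 16 of the first set with positions 5 to 7 and 13 to 16 of the second against the others. It was picked as the highest, and whether it reflects a structure of the libraries apart from the sets was not tested. No biological explanation was tested.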
